A study of Mus musculus with 2 samples.

How the data were processed

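The study holds 2 single-cell libraries of sorted synovial myeloid cells from mouse ankle joints, 1 per group: untreated chimeras (steady state) and chimeras 7 days after 200 µL of clodronate liposomes. The animals were CD45.2 mice given CD45.1 bone marrow with the ankle shielded, and CD45+ CD11b+ cells without the surface antigens Ly6C, CD177, MHC class II, CD64, Ly6G and SiglecF were sorted, per the labels' protocols. The deposited values were raw UMI counts per gene and per antibody barcode in each cell barcode, made by the authors with Cell Ranger 6.1.2 against mm10, per the submitters' processing notes. The same notes name Seurat 4.4.0 without saying what it was used for. The matrices held 32285 genes and 92 antibodies, and the values were integers. The lowest RNA count of a deposited barcode was 502 in the steady-state library and 500 in the day 7 library. The labels do not say how many animals were pooled, or give sort yields.

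Cells with at least 500 RNA UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept, and doublets called by Scrublet within each library (through scanpy) were removed. Of 1912 steady-state barcodes, 45 had fewer than 200 genes and 271 (14.2%) exceeded the mitochondrial limit; 1637 passed and 7 of these were called doublets. Of 1277 day 7 barcodes, 11 and 63 (4.93%) failed these filters; 1210 passed and 9 were called doublets. This left 1630 cells with a median of 2885.5 genes and 1201 cells with a median of 2598 genes. Cells with at least 20 counts of both CD45.1 and CD45.2 numbered 31 and 0.

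Cells of both libraries were clustered together on RNA without integration (scanpy 1.11.5, igraph 0.11.9): counts scaled to 10000 per cell, log-transformed, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0 and a fixed seed. A cluster was named after 1 of 21 cell type marker lists, with "-like", from the list with the highest mean fold among those with at least 3 markers detected in at least 25% of its cells. That list also needed a marker among the cluster's 10 leading genes (for cDC2 one outside class II), no list could have more leading markers, and clusters with a low median depth stayed unnamed. The marker lists were fixed before the data were examined, but details of the naming rule were set after the clusters had been seen, so the shares of unnamed clusters are given too. The progenitor-like cluster had 4 progenitor and 4 neutrophil markers among its leading genes. No cluster labels of the authors were available.

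Origin was set from the antibody counts. For each cell d was the log2 ratio of CD45.2 to CD45.1 counts, each plus 1. A Gaussian mixture of 2 components (sklearn 1.9.0) was fitted to d over both libraries, with means of 4.03 and -2.83. Cells with a posterior of at least 0.95 for the higher component were called host-class, those at or below 0.05 donor-class, and the rest unassigned. The highest d of a donor-class cell was 0 and the lowest of a host-class cell 2.36. Cells with few counts of both antibodies have d near 0, so they fall in the donor class or stay unassigned.

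UMIs were summed over the cells of a group and scaled to 1000000 (CPM), and log2 ratios were computed for genes with at least 20 CPM in either group. Ratios were made for day 7 over steady state in all cells, in Ly6C-low monocyte-like cells, in classical monocyte-like cells and in macrophage-like cells, and for host-class over donor-class macrophage-like cells in each library. The same day 7 ratios were made within host-class and within donor-class cells. The plan named the comparison after Ly6C-low monocyte-like cells but defined it by the largest monocyte-like class, which was the classical one, so both were run. Host-class and donor-class cells were to be compared in that class too; it held 1 host-class cell at steady state, so the macrophage-like class was used instead.

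With 1 library per group no test across libraries was possible. Shares have exact Clopper-Pearson intervals and ratios conditional exact Poisson intervals (95%; scipy 1.17.1), which cover counting error alone. A group with 0 counts was set to 3 counts, the number a zero allows, to give a lower bound of a ratio. For gene lists the median log2 ratio of members past the CPM minimum was ranked among 10000 random lists of the same size matched on mean expression in 20 bins; the percentile describes these libraries and is no test. Lists with fewer than 3 such members have no median. Of 41 lists, 28 had a median in all cells, 25 in Ly6C-low monocyte-like cells, 24 in classical monocyte-like cells, 26 in macrophage-like cells, and 24 at steady state and 27 at day 7 in host-class over donor-class cells. Antibody counts were given as medians per cell and per 10000 antibody counts.

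Named genes were the 12 highest and 12 lowest in each comparison by the interval bound nearest to no change, leaving out ribosomal, mitochondrial, Gm, Rik and antibody features. For host-class over donor-class the smaller of the bounds of both libraries was used. Members of the lists and genes of the sort antigens were named as well. Genes withheld for evaluation are not reported here. The antibodies named are the 6 that rose and the 6 that fell most by the same bound over all cells, among those above a minimum of summed counts.

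The ratio step was tested on simulated counts drawn from the real means, with 200 genes changed in 20 simulations. The simulated counts were Poisson, as the interval assumes, and held no spread between cells. They check the computation and do not give coverage or detection rates for the real data. In the simulation of all cells (6021 genes) 95.08% of intervals held the true value, and 99.9% of genes changed 1.5-fold had intervals excluding no change. For Ly6C-low monocyte-like cells (5534 genes) these were 95.7% and 61.3%, with 90.5% at 2-fold and 99.5% at 4-fold. For host-class over donor-class cells (6221 genes) they were 95.61% and 56.6%, with 81.3% at 2-fold. Of 200 random lists 8.0%, 4.5% and 6.5% fell outside the middle 95% in the 3 simulations.

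Alternatives tried were: a mixture per library, a fixed threshold at 1 and -1, no unassigned zone (posterior 0.5) and only monocyte-like and macrophage-like cells for origin; resolution 0.5 and 1.5, doublet calls kept, a stricter filter (1000 UMIs, 5% mitochondrial) and thinning to 1100 UMIs per cell for class shares. For ratios and lists they were median-ratio scaling, equal weight per cell, a minimum of 100 CPM, no minimum (10 UMIs) and doublet calls kept; for all cells also equalised class shares; for antibodies the centred log ratio and unscaled medians. Chosen after seeing the data were: no cell filter, the classical monocyte-like and macrophage-like comparisons, clusters 4 and 7 alone, clear CD45 counts, at least 5 CD45 counts, and macrophage-like cells without mast cell UMIs. Alternatives were run for the genes named in the text and for the lists. Antibody levels were compared between libraries with care, since staining differed; antibodies with almost no counts were not used, CD45 and CD64 among them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.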

Results

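Synovial myeloid cells of the mouse ankle joint were profiled by CITE-seq. The method reads a cell's messenger RNA together with barcoded antibodies bound to its surface. The animals were bone marrow chimeras: CD45.2 mice had received CD45.1 marrow while the ankle was kept out of the radiation field. CD45.2 thus marks cells of the host and CD45.1 marks cells that came from the donor marrow. One library came from untreated chimeras (steady state). The other came from chimeras taken 7 days after an injection of 200 µL of clodronate liposomes, which kill the phagocytes that ingest them, behind the eye. Cells had been sorted as positive for CD45 and CD11b and negative for Ly6G, SiglecF, CD64, MHC class II, Ly6C and CD177. After filtering, 1630 steady-state cells with 17071067 UMIs (median 9563.5 per cell) and 1201 day 7 cells with 10857623 UMIs (median 8315) remained. With 1 library per group there is no replicate check on any difference between the groups. Unless given as list members or alternatives, the ranges are 95% intervals of counting error only, exact Clopper-Pearson for shares and exact Poisson for ratios. They do not cover differences between animals, sorts or preparations. Those of ratios treat each UMI as independent, so they also leave out the spread between cells of a group.

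The first comparison asked which cells, of which origin, the synovium held before and after clodronate. Macrophage-like cells, rich in complement C1q, Lyve1 and Timd4 transcripts, made up 44.6% of the steady-state cells (42.2 to 47.1%, 727 of 1630) and 11.1% at day 7 (9.35 to 12.99%, 133 of 1201). Classical monocyte-like cells went the other way, from 6.32% (5.19 to 7.61%) to 31.0% (28.4 to 33.7%). Ly6C-low monocyte-like cells, the patrolling kind, rose from 8.10% (6.82 to 9.53%) to 14.2% (12.3 to 16.3%). Cells like conventional type 2 dendritic cells (cDC2-like) fell from 10.98% to 2.41% and fibroblast-like cells from 4.17% to 1.42%. Progenitor-like cells, with transcripts of the granule proteases of immature granulocytes and monocytes, rose from 0.245% (4 cells) to 10.8% (130 cells), and neutrophil-like cells from 0.123% to 2.66%. At resolution 0.5 and with thinned cells these 2 classes formed 1 neutrophil-like class, 12.3% and 11.1% of day 7 cells. A group of 8 basophil-like cells held day 7 cells alone; at resolution 1.5 cells with its leading genes sat in a mast cell-like cluster of 1 steady-state and 11 day 7 cells.

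Host-class cells were 50.4% of the cells with an assigned origin at steady state (47.8 to 52.9%, 764 of 1516 cells) and 11.5% at day 7 (9.64 to 13.5%, 127 of 1109); with the fixed threshold they were 54.5% and 18.99%. Origin differed between cell classes. Host-class cells were 91.9% of the assigned macrophage-like cells at steady state (616 of 670) and 91.8% at day 7 (90 of 98), while 57 of 727 and 35 of 133 cells of the class had no assigned origin. Unnamed cluster 7 (117 and 28 cells) was of mixed origin, 69.7% host-class at steady state (76 of 109 assigned) and 36.8% at day 7 (16.3 to 61.6%, 7 of 19). Its cells at day 7 had medians of 3 CD45.1 and 3 CD45.2 counts and 2743.5 UMIs, and 9 were unassigned. At steady state the medians were 2, 47 and 9802. Weakly stained cells are called donor-class or left unassigned, so weak staining may account for the lower share of cluster 7 at day 7. The other large named classes were mostly donor-class. Host-class cells were 0.980% of classical monocyte-like cells at steady state and 3.54% at day 7. They were 0% (0 of 129, which allows up to 2.33%) and 1.79% in Ly6C-low monocyte-like cells, 9.20% and 7.41% in cDC2-like cells, and 1.69% in progenitor-like cells at day 7. Origin was left open for 114 steady-state and 92 day 7 cells.

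**Figure D1:**
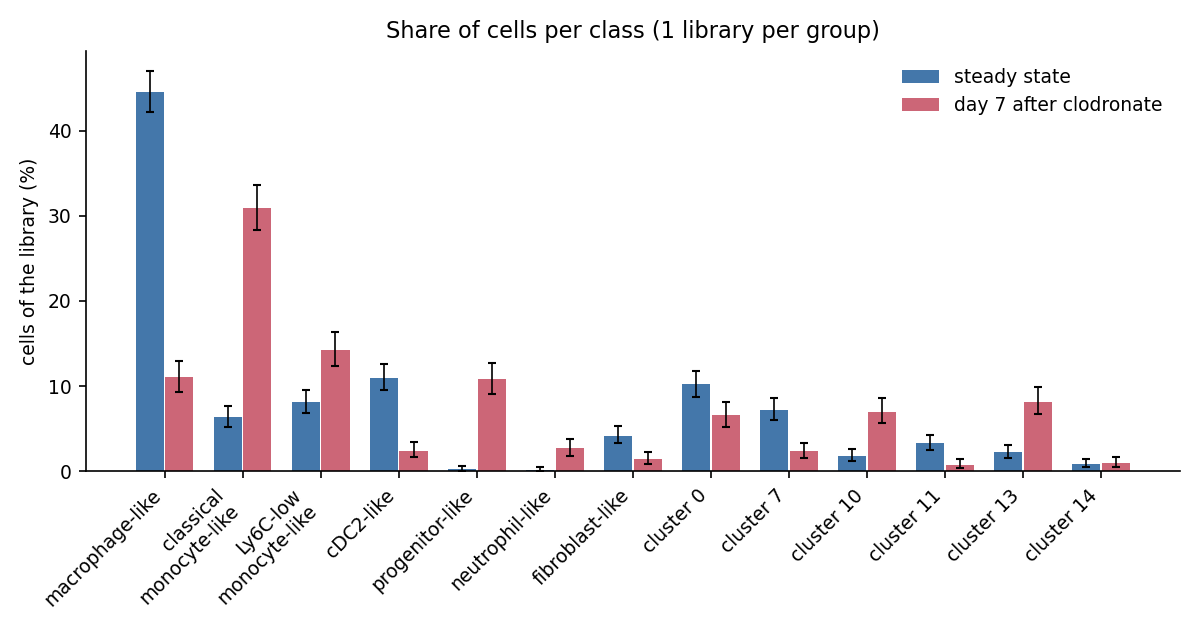
Share of cells per class in percent of all filtered cells of a library (y axis) for each class or unnamed cluster (x axis), 1 library per group; bars start at 0 and error bars are exact 95% binomial intervals. Macrophage-like cells stand at 44.6% in the steady-state library and 11.1% in the day 7 library, classical monocyte-like cells at 6.32% and 31.0%; the 8 basophil-like cells of day 7 are not drawn.

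These shares describe what passed the sort. The gate had excluded Ly6C, MHC class II, CD177 and CD64, the product of Fcgr1, which is on the macrophage marker list. It had also required CD45 and CD11b. Yet the Ly6C antibody had a median of 57 counts in classical monocyte-like cells at steady state and 57.5 at day 7. Cd177 transcripts rose from 15.1 to 132 CPM (counts scaled to a total of 1000000 per group) over all cells. Fibroblast-like cells had medians of 0 CD45.1 and 1 CD45.2 counts at steady state, so they should hardly pass a gate on CD45. The shares, those of macrophage-like and fibroblast-like cells included, can thus move with how each sort ran. Naming depended on the clustering: across its alternatives the macrophage-like share lay between 28.6% and 52.4% at steady state and between 7.27% and 13.5% at day 7. The classical monocyte-like share lay between 1.46% and 8.04% and between 18.5% and 42.1%. Clusters 0, 7, 10, 11, 13 and 14 stayed unnamed. They held 10.2%, 7.18%, 1.78%, 3.25%, 2.21% and 0.859% of the steady-state cells and 6.58%, 2.33%, 6.99%, 0.749%, 8.16% and 0.916% of the day 7 cells.

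**Figure D2:**
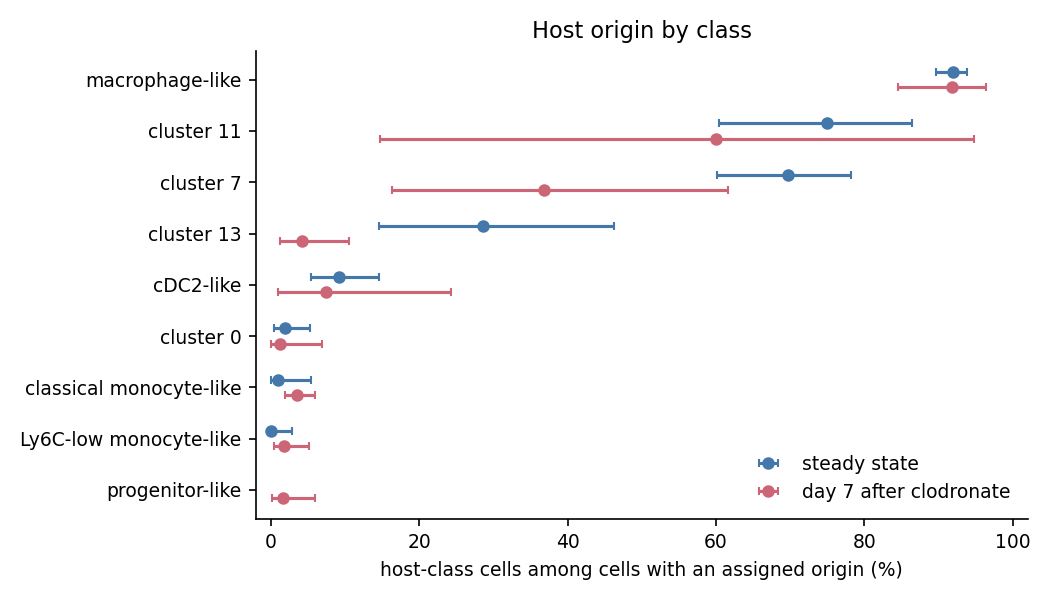
Host-class cells in percent of the cells with an assigned origin (x axis) per class or unnamed cluster (y axis), with exact 95% binomial intervals, for the steady-state and the day 7 library. Macrophage-like cells sit at 91.9% and 91.8%, and classical and Ly6C-low monocyte-like cells at or below 3.54% in both libraries.

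Over all cells, the day 7 library was rich in granule genes of immature granulocytes and poor in markers of macrophages and fibroblasts and in class II antigen presentation genes. Mpo (ENSMUSG00000009350), the granule myeloperoxidase, was 598-fold higher at day 7 (350 against 0.586 CPM; log2 ratio 9.22, 8.34 to 10.29), and the granule proteases Elane, Ctsg and Prtn3 were 174-fold, 137-fold and 65.2-fold higher. Retnlg, Ms4a3, the antimicrobial gene Camp and the ficolin gene Fcnb were 181-fold, 43.8-fold, 26.7-fold and 29.4-fold higher, Nkg7, Itgb2l and Wfdc21 78.1-fold, 43.5-fold and 37.0-fold. Olfm4 had 0 UMIs at steady state and 504 at day 7, at least 264-fold higher against a floor of 3 counts. Progenitor-like and neutrophil-like cells, in which these genes are concentrated, went from 0.245% and 0.123% to 10.8% and 2.66% of cells.

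Genes of connective tissue fell: Prg4, which encodes the joint lubricant lubricin, was 300.4-fold lower (332 to 1.11 CPM), the cartilage matrix gene Comp 49.0-fold, and the collagen genes Col1a1, Col3a1 and Col1a2 13.8-fold, 11.5-fold and 10.5-fold. Bgn and Myoc were 14.4-fold and 12.02-fold lower, and Htra4, a serine protease gene with 383 of its 451 steady-state UMIs in fibroblast-like cells, 47.8-fold. Fibroblast-like cells, which carried Prg4 at 8462 CPM at steady state, went from 68 to 17 cells, so these falls rest on few cells. Sparc, 9.44-fold lower, had 4921 of its 15801 steady-state UMIs in fibroblast-like and 10608 in macrophage-like cells. Genes seen mostly in macrophage-like cells also fell, the arginase gene Arg1 31.1-fold and Tmem37 11.6-fold. The cysteine protease gene Ctsk, strongest in unnamed cluster 7 (1286 CPM at steady state), was 14.9-fold lower.

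By gene list, 15 of 15 macrophage markers were lower, with a median log2 ratio of -2.44 (percentile 0 of 10000 random lists matched on expression). C1qa (ENSMUSG00000036887), a chain of the complement component C1q, had a log2 ratio of -3.11 (-3.16 to -3.06). Complement genes (9 of 11 lower, median -1.61), scavenger and efferocytosis receptors (12 of 15 lower, median -1.82; Timd4, a receptor for dying cells, -2.82), genes of alternative activation (9 of 11 lower, median -2.25; Retnla -2.69) and osteoclast differentiation genes (7 of 8 lower, median -0.96) lay at percentiles of 0.04 or below. Of the class II antigen presentation genes 6 of 6 were lower (median -1.98; Cd74, the invariant chain, -1.90). So were 15 of 18 lysosome genes (median -0.46; Lgmn -1.74) and 16 of 17 immediate early genes, which also respond to tissue dissociation (median -0.66; Jun -1.70, Hspa1a -1.91). Cell cycle genes were higher in 17 of 18 cases (median 1.54; Top2a 2.57, Hmgb2 2.46).

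Marker lists of other cells moved with the shares: neutrophil markers 11 of 11 higher (median 3.91), progenitor markers 5 of 6 higher (6.56), classical monocyte markers 8 of 10 higher (1.35), Ly6C-low monocyte markers 10 of 13 higher (0.78), cDC2 markers 8 of 8 lower (-1.98), fibroblast markers 7 of 7 lower (-3.39) and osteoclast markers 2 of 3 lower (-2.25). The other 12 lists with a median stayed within the middle 95% of random lists. Their medians were 0.09 for nonclassical monocyte regulators, 0.30 for interferon-stimulated genes, 0.33 for inflammatory cytokines and chemokines, -0.07 for class I antigen presentation, -0.30 for lipid handling, -0.09 for hypoxia and glycolysis, 0.28 for adhesion receptors, -0.28 for growth factor receptors, -0.40 for Fc receptors, 0.11 for matrix remodelling, -0.40 for iron and heme and 0.59 for cDC1 markers. For 13 lists fewer than 3 members were compared, so they have no median: the sex chromosome list and the markers of T cells, B cells, NK cells, innate lymphoid cells, plasmacytoid and migratory dendritic cells, mast cells, basophils, eosinophils, endothelium, erythroid cells and platelets. When the classes were given equal shares in both libraries, the macrophage marker median shrank to -0.63, and the medians of the cell cycle, scavenger receptor and Ly6C-low marker lists turned to -0.11, 0.05 and -0.28.

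Genes of the sort antigens were read as a check on the gate. Ly6c2 rose 7.72-fold (152 to 1175 CPM), Cd177 8.73-fold and Ptprc, which encodes CD45, 2.00-fold, while H2-Ab1 was 4.65-fold lower (733 to 158 CPM) and Ly6c1 4.84-fold lower. Ly6g had 0 UMIs at steady state and 104 at day 7 (at least 54.5-fold higher), Siglecf 5 and 17 UMIs. Itgam, the gene of CD11b, had a log2 ratio of -0.19, which became 0.19 with equal class shares, and Fcgr1, the gene of CD64, one of -0.07 (-0.26 to 0.12).

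Within Ly6C-low monocyte-like cells (132 at steady state, 171 at day 7), the libraries were compared inside 1 class. At day 7 these cells carried more transcripts of matrix remodelling and classical monocyte genes and fewer of antigen presentation, Fc receptor and immediate early genes. Hmox1 (ENSMUSG00000005413), the heme oxygenase that breaks down heme, was 5.60-fold higher (78.0 to 437 CPM; log2 ratio 2.49, 2.14 to 2.84), and Gclm, a subunit of the enzyme for glutathione synthesis, 8.01-fold higher. The stress cytokine gene Gdf15 went from 2 to 69 UMIs (log2 ratio 4.74, 2.83 to 7.81) and the membrane metalloprotease gene Mmp14 from 0 to 56 UMIs, at least 14.4-fold higher. The formyl peptide receptor gene Fpr2, the proteoglycan gene Vcan, Chil3, Cstb and Ikbke were 10.6-fold, 13.4-fold, 4.27-fold, 4.01-fold and 6.26-fold higher. The mix within the class was not the same in both libraries: at resolution 1.5 it split into a cluster of 104 steady-state and 57 day 7 cells and another of 33 and 118. Fabp5, a fatty acid carrier, was 4.82-fold higher but turned to a log2 ratio of -0.61 when doublet calls were kept and the cells clustered anew.

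Heat shock genes Hspa1a and Hspa1b had log2 ratios of -4.28 (-6.20 to -2.85) and -3.96 in these cells, and Egr1 one of -3.13. The transcription factor gene Ets1 was 12.8-fold lower, Plxna4os1 11.7-fold, Pglyrp1, a peptidoglycan recognition gene typical of Ly6C-low monocytes, 5.02-fold. Lilra5 was 5.71-fold lower, Hpgd 5.20-fold, the chemokine gene Cxcl2 4.44-fold and the lymphotoxin gene Ltb 5.37-fold. The lipid carrier gene Apoe was 3.84-fold lower; at steady state it stood higher in these cells (2878 CPM) than in macrophage-like cells (988 CPM). Pf4 was 5.59-fold lower, but macrophage-like cells, with 2881 CPM of Pf4, fell from 44.6% to 11.1% of cells, and fibroblast-like cells went from 42.4 to 0 CPM.

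Among the lists, all 6 class II genes were lower (median -1.13, percentile 0; Cd74 -1.08, H2-Eb1 -1.94). So were 8 of 9 class I genes (median -0.49; H2-D1 -1.06), 5 of 6 Fc receptor genes (median -0.85; Fcgr4 -1.69, Fcer1g -0.40). Also lower were 14 of 16 immediate early genes (median -1.19; Jund -1.45), 7 of 11 inflammatory genes (median -0.44) and 8 of 10 regulators of nonclassical monocytes (median -0.53). Nr4a1, the transcription factor on which Ly6C-low monocytes depend, had a log2 ratio of -0.58 and Klf2 one of -1.25. Markers of Ly6C-low monocytes were lower in 12 of 14 cases (median -0.51) and markers of classical monocytes higher in 9 of 10 (median 0.74); Ly6c2 rose 3.07-fold. Macrophage markers (6 of 7 lower, median -0.94) and cDC2 markers (4 of 5 lower, median -1.18) were also below the middle 95%. The lower cDC2 markers were all class II genes, and Tnip3 was higher. Macrophage-like and cDC2-like cells fell from 44.6% to 11.1% and from 10.98% to 2.41% of cells. Less RNA outside cells at day 7 was thus not excluded as a source of the falls in these lists and in class II. Matrix remodelling genes were higher in 7 of 8 cases (median 1.22, percentile 100; Fn1 1.20, Thbs1 1.22) and alternative activation genes in 3 of 3 (median 1.32), though the latter median was -0.50 with doublet calls kept. Genes of iron and heme were higher in 8 of 8 cases (median 0.31; Fth1 0.38, Ftl1 0.17) at percentile 96.6, within the middle 95%, as were 11 further lists.

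Camp and S100a8, both granulocyte genes, were 26.3-fold and 12.7-fold higher in Ly6C-low monocyte-like cells, and neutrophil markers had a median of 2.45, which fell to 0.33 with equal weight per cell. RNA outside cells is a background for these genes. S100a8 stood at 101 CPM in Ly6C-low monocyte-like cells at day 7, with a UMI in 28.65% of cells at a median depth of 7375 UMIs. In 2 classes that should lack it, S100a8 stood at 94.1 CPM (8 UMIs in 17 fibroblast-like cells, 23.5% of cells, median depth 5957 UMIs) and 30.3 CPM (133 macrophage-like cells, 20.3% of cells, median depth 6802 UMIs), so background was not excluded as the source of the rise. Progenitor-like cells of that library had 97943 CPM of S100a8.

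Classical monocyte-like cells, the largest monocyte-like class (103 at steady state, 372 at day 7), carried fewer interferon-stimulated, inflammatory and immediate early transcripts at day 7, and the medians of macrophage and neutrophil markers moved furthest (-1.20 and 1.60). Cxcl10 (ENSMUSG00000034855), an interferon-induced chemokine, was 10.0-fold lower (151 to 15.1 CPM; log2 ratio -3.32, -3.81 to -2.86), the interferon-induced GTPase gene Gbp5 12.1-fold, the chemokine gene Ccl4 6.43-fold and the cytokine signalling inhibitor Socs3 6.50-fold. Cxcl10 was carried by few cells, with a UMI in 4.85% of the class at steady state. The mix within the class differed between the libraries: at resolution 1.5 it held 64 and 301 cells, beside a cluster led by interferon-stimulated genes of 45 and 76 cells, and with the stricter filter 29 and 262 beside 71 and 80. Jun, Atf3, Klf2, Ckb and Ubb were 3.89-fold, 2.54-fold, 2.57-fold, 3.31-fold and 2.47-fold lower. C1qa, C1qc and Pf4 were 41.7-fold, 5.15-fold and 8.42-fold lower. C1qa stood at 35.8 CPM in these cells at steady state, close to the 27.3 CPM of fibroblast-like cells, which should lack it, and at 5267 CPM in macrophage-like cells.

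Interferon-stimulated genes were lower in 9 of 11 cases (median -0.52, percentile 0.02; Ifitm3 -0.53, Irf7 -1.11), immediate early genes in 12 of 14 (median -0.64), and inflammatory genes in 6 of 10 (median -0.35). Lower too were class I genes in 6 of 8 (median -0.40; H2-D1 -1.18), and class II genes in 6 of 6 (median -0.39; Cd74 -0.09, -0.20 to 0.01). The same held for Fc receptor genes in 5 of 5 (median -0.46; Fcer1g -0.35) and regulators of nonclassical monocytes in 7 of 10 (median -0.31). Ly6C-low monocyte markers (6 of 11 lower, median -0.37) and macrophage markers (6 of 7 lower, median -1.20) were below the middle 95% as well. Matrix remodelling genes were higher in 7 of 8 cases (median 0.54; Thbs1 0.84, Fn1 0.65). With the neutrophil markers below, 11 of 24 lists lay outside the middle 95% and 13 within it.

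Higher in classical monocyte-like cells at day 7 were Vcan (4.66-fold), the cholesterol exporter gene Abca1 (8.33-fold, 3 against 92 UMIs), B4galt6 and Lcn2 (each 5.47-fold), Xlr (6.04-fold), Ell2 (4.24-fold), the superoxide dismutase gene Sod1 (2.61-fold) and Arhgef10l (2.82-fold). The granulocyte genes S100a9, S100a8, Camp and Wfdc21 were also higher, S100a9 72.2-fold (2 against 532 UMIs), S100a8 10.2-fold, Camp 5.61-fold and Wfdc21 at least 8.06-fold, and neutrophil markers were higher in 7 of 8 cases (median 1.60). S100a8 stood at 278 CPM here at day 7 with a UMI in 45.7% of cells (median depth 9271 UMIs), against 94.1 CPM and 23.5% in fibroblast-like cells (median depth 5957 UMIs), and Camp at 35.4 CPM against 35.3 CPM. Ly6c2 rose 1.22-fold.

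**Figure D3:**
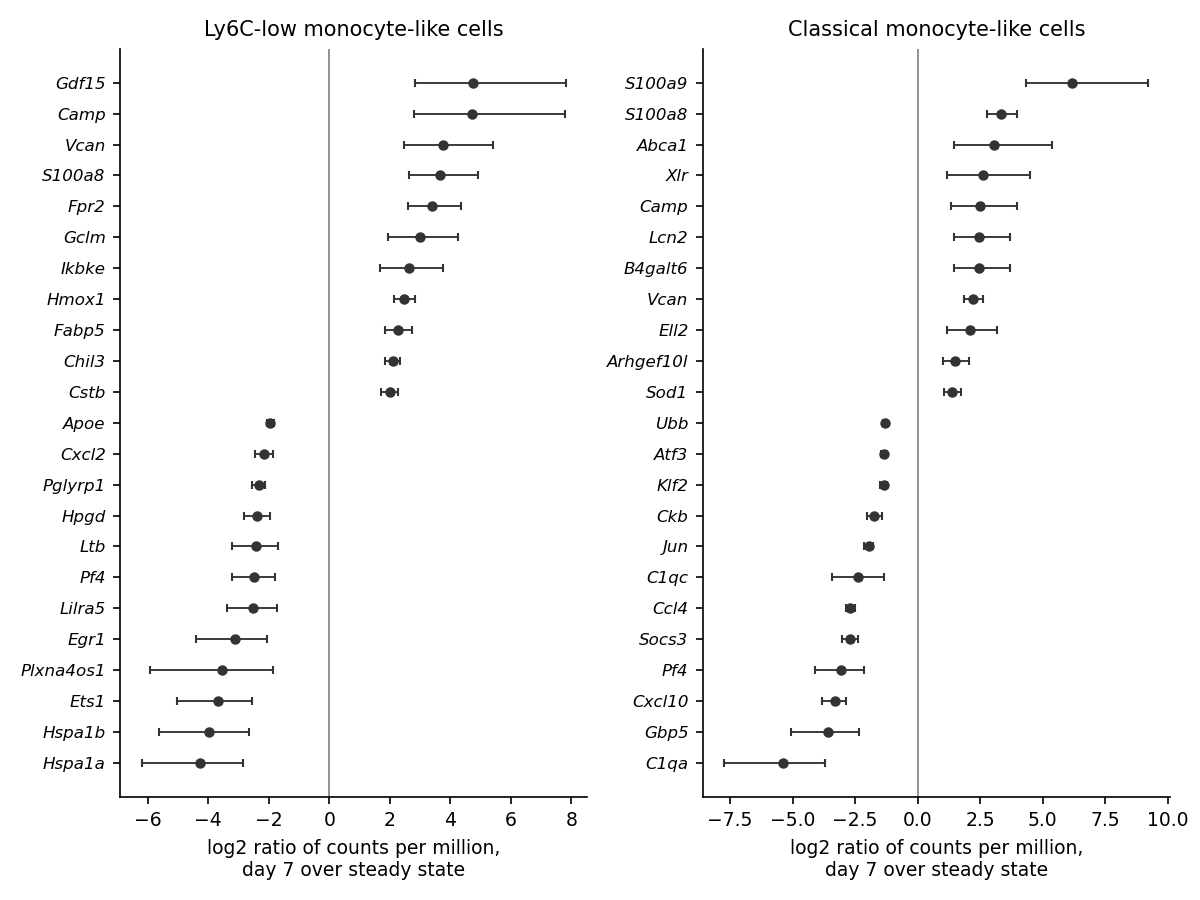
Log2 ratio of CPM, day 7 over steady state (x axis), for the named genes of each monocyte-like class (y axis), with exact 95% counting intervals; genes with 0 UMIs in a library are not drawn. In Ly6C-low monocyte-like cells Hmox1 lies at 2.49 and Hspa1a at -4.28; in classical monocyte-like cells Cxcl10 lies at -3.32.

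The macrophage-like cells that remained at day 7 (133, against 727 at steady state) carried fewer transcripts of lysozyme, of macrophage markers and of osteopontin. The class pools clusters 1 to 4, which held 232, 158, 120 and 217 cells at steady state and 23, 36, 29 and 45 at day 7, and its median depth was 10166 and 6802 UMIs, and the mix of clusters thus differed between the libraries. Lyz2 (ENSMUSG00000069516), a lysozyme gene, was 2.65-fold lower (8255 to 3119 CPM; log2 ratio -1.40, -1.46 to -1.35) and Lyz1 3.18-fold lower. Spp1, the gene of osteopontin, was 13.9-fold lower, Arg1 7.33-fold, Il1b 4.98-fold, Cxcl1 3.20-fold and the lysosomal glycoprotein gene Cd68 2.31-fold. H2-Aa, Tmem37, Syngr1, AY036118 and Ubb were 3.34-fold, 2.64-fold, 2.74-fold, 2.45-fold and 2.21-fold lower. Macrophage markers were lower in 11 of 15 cases (median -0.59, percentile 0; C1qa -0.73, C1qb -0.77) and class II genes in 6 of 6 (median -1.07; Cd74 -0.98). Also lower were cDC2 markers in 4 of 6 cases (median -1.07; the 4 were class II genes, and Tnip3 and Mgl2 were higher), lysosome genes in 15 of 18 (median -0.32; Ctsd -0.84) and Fc receptor genes in 5 of 5 (median -0.45). Inflammatory genes were higher in 7 of 11 cases (median 0.36, percentile 99.0; Ccl2 0.55) and immediate early genes in 11 of 17 (median 0.21, percentile 97.9; Zfp36 0.58, Hspa1b 1.29). Besides these and the neutrophil and mast cell markers (medians 3.62 and 5.65), 17 lists stayed within the middle 95%. The median log2 ratio of all compared genes in this class was 0.10, against which these values should be read.

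Egr3, an immediate early transcription factor gene, and Nabp1 were 3.06-fold and 3.53-fold higher in macrophage-like cells at day 7. Ccr2 and Plac8, both monocyte genes, were 2.97-fold and 4.84-fold higher, but had log2 ratios of 0.02 and 0.26 with doublet calls kept and the cells clustered anew. Mast cell genes and Il1rl1 also stood higher, Mcpt4 55.7-fold, Cma1 44.96-fold, Tpsb2 56.5-fold, Cpa3 25.1-fold and Il1rl1 6.76-fold. These came from 3 of 133 day 7 cells and 1 of 727 steady-state cells with at least 5 mast cell UMIs; without them the log2 ratio of Mcpt4 went from 5.80 to 1.46. S100a9 and Camp were 13.2-fold and 12.3-fold higher, with S100a9 at 72.1 CPM against 58.8 CPM in fibroblast-like cells of the same library.

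By origin, the falls within macrophage-like cells held among host-class cells alone (616 and 90 cells), with log2 ratios of -1.42 for Lyz2, -2.87 for Spp1, -1.21 for Cd68 and -0.70 for C1qa, and rises of 0.68 for Zfp36 and 0.77 for Ccl2. H2-Aa gave -0.46 (-1.24 to 0.24) in host-class cells against -1.74 in the whole class, and Plac8 0.01 (-2.35 to 1.71) against 2.28. Donor-class macrophage-like cells at day 7 numbered 8, so no such ratios are given for them. Classical and Ly6C-low monocyte-like cells had almost no host-class cells, and in donor-class cells alone Hmox1 was 5.64-fold higher and Nr4a1 had a log2 ratio of -0.59 in the Ly6C-low class; Ifitm3 gave -0.52 and Thbs1 0.82 in the classical class.

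Host-class and donor-class macrophage-like cells were compared within each library, to see how cells of the host differ from those the donor marrow gave. Summed over their cells (54 at steady state), donor-class cells carried far more antigen presentation transcripts. Cd74 (ENSMUSG00000024610) was 11.3-fold lower in host-class than in donor-class cells at steady state (142 against 1600 CPM, log2 ratio -3.49, -3.63 to -3.36). At day 7, where the donor-class side rests on 8 cells, Cd74 was 13.3-fold lower. The MHC class II antibody then stood at 21.1 per 10000 in host-class and 267 in donor-class cells, but with medians of 1 and 0.5. The donor-class level was thus unevenly spread over the 8 cells, and the typical one was not higher. The MHC class II antibody counts of donor-class cells at steady state were unevenly spread, with 69.9% in 5 of the 54 cells. The adhesion protein gene Emb, Napsa, Rab11fip1 and Tnip3 were 25.8-fold, 15.1-fold, 18.97-fold and 14.6-fold lower in host-class cells at steady state. Lower too were the monocyte chemokine receptor gene Ccr2 5.55-fold, the lectin gene Mgl2 5.21-fold, the growth factor gene Areg 4.401-fold, Cd93 4.76-fold, Dusp5 5.19-fold, the lipase gene Lpl 3.41-fold and the perforin-like gene Mpeg1 3.48-fold.

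Host-class cells were richer in Vsig4 (ENSMUSG00000044206), a complement receptor of resident macrophages, 3.15-fold (1642 against 522 CPM; log2 ratio 1.65, 1.47 to 1.84), in Lyve1 2.46-fold, in the arginine transporter gene Slc7a2 2.92-fold and in the matrix genes Sparc, Olfml3, Pcolce2 and Timp2 2.80-fold, 3.60-fold, 2.52-fold and 1.98-fold. Fcgrt, the recycling receptor for immunoglobulin G, Fermt2, Pmepa1 and Ltc4s were 2.96-fold, 4.39-fold, 2.5-fold and 2.37-fold higher. Vsig4, Lyve1, Slc7a2, Sparc, Olfml3, Pcolce2, Pmepa1 and Ltc4s are among the leading genes of clusters 1 or 2. These clusters held 208 and 150 host-class but 3 and 0 donor-class cells at steady state, so cluster position may account for part of these differences.

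All 6 class II genes were lower in host-class cells at steady state (median -3.02, percentile 0; H2-Eb1 -3.55, H2-Ab1 -2.14), as were 7 of 7 cDC2 markers (median -3.32). So were 9 of 12 inflammatory genes (median -0.64; Cxcl2 -1.50, Il1a -2.64), 14 of 17 immediate early genes (median -0.38; Zfp36 -0.84) and 2 of 3 innate lymphoid cell markers (median -2.14). Scavenger receptors were higher in 10 of 13 cases (median 0.62; Timd4 3.57, Colec12 1.90), macrophage markers in 13 of 15 (median 0.55), complement genes in 8 of 9 (median 0.40; C1qa 0.40) and classical monocyte markers in 4 of 5 (median 0.37). The other 15 lists with a median stayed within the middle 95%. The class holds 54 donor-class cells at steady state, 39 of them in cluster 4; within that cluster (170 host-class, 39 donor-class cells) the class II median was -1.76, and the classical monocyte marker median turned to -0.31. The immediate early and complement medians there were -0.13 and 0.18 (percentiles 3.09 and 92.1), within the middle 95%. In unnamed cluster 7 (76 and 33 cells) the class II, inflammatory and immediate early medians were -0.78, 0.03 and 0.07. With doublet calls kept the class held 17 donor-class cells, its class II median was -4.37, and the inflammatory, immediate early, complement and classical monocyte medians turned to 0.52, 0.34, -0.02 and -0.21.

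At day 7, with 8 donor-class cells, the class II median was -1.71 (members from -3.74 to 0.55, 5 of 6 lower), and the macrophage marker and complement medians were 0.52 and 0.66. The scavenger receptor and immediate early medians, 0.36 and -0.02, were within the middle 95% (percentiles 96.5 and 68.1). The inflammatory median was -0.51, also within the middle 95% (percentile 3.23), and the classical monocyte marker median was -3.20, opposite to steady state. The Ly6C antibody stood at 494 per 10000 in donor-class and 36.9 in host-class cells at day 7, with medians of 3.5 and 3. A few of the 8 donor-class cells may thus set the classical monocyte marker median. With equal weight per cell, 3 of the genes higher in host-class cells turned at day 7: Vsig4 to -0.41, Pcolce2 to -0.77 and Timp2 to -0.06. For Tim4, surface protein followed the transcripts at steady state. Median antibody counts per cell in host-class and donor-class cells were 77.5 and 2 for Tim4, the product of Timd4, 82 and 23.5 for folate receptor beta (FrB), and 2 and 9 for MHC class II, and the levels per 10000 antibody counts differed the same way (log2 ratio 2.65, 1.25 and -3.52). CD163 had medians of 131 and 10 but equal levels per 10000 antibody counts (1906.5 and 1912.2), so its median reflects how the counts were spread over cells. The MHC class II counts of donor-class cells were also unevenly spread: 5 of the 54 cells held 69.9% of them, and the mean was 67.9.

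Of the antibodies over all cells, per 10000 antibody counts, MHC class II fell from 484 to 94.97, Tim4 from 391 to 83.0, CD80 from 133 to 42.6, CD86 from 322 to 108, FrB from 543 to 207 and CD45.2 from 240 to 97.3. Ly6C rose from 97.2 to 697, Ly6G from 7.19 to 48.4, CD62L from 5.55 to 39.3, CD215 from 1.47 to 13.98, CD186 from 1.47 to 14.99 and CD200r3 from 0.840 to 42.3. Centred log ratios per cell are in natural log units, so their sizes cannot be set directly against the log2 ratios of the levels, given in parentheses. Their changes were -0.58 for MHC class II (-2.35) and -0.77 for Tim4 (-2.23). They were 0.85 for Ly6G (2.75), 0.67 for CD62L (2.83), 0.44 for CD215 (3.25), 0.48 for CD186 (3.35), 1.104 for CD200r3 (5.65) and 2.33 for Ly6C (2.84). For CD80, CD86, FrB and CD45.2 they were -1.59, -1.65, -2.21 and -1.43. Staining differed between the libraries: the median antibody count per cell was 1050 at steady state and 543 at day 7. Summed over 8 lymphocyte antibodies, whose targets most of these cells should lack, the level was 24.995 and 107 per 10000. These are sums over the 8, so they cannot be set directly against the level of a single antibody. The panel held no isotype controls, so the low levels that rose at day 7, such as CD215, CD186 and CD200r3, cannot be separated from background.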

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

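The differences in this part were looked at only after the results were seen, and none of them was tested. Inflammatory genes had a median log2 ratio of 0.36 in macrophage-like cells at day 7 over steady state, but -0.44 in Ly6C-low monocyte-like cells, a difference of 0.8, and -0.35 in classical monocyte-like cells, a difference of 0.71. Immediate early genes had medians of 0.21 in macrophage-like cells against -1.19 in Ly6C-low monocyte-like cells, a difference of 1.4, and -0.64 in classical monocyte-like cells, a difference of 0.85. They are listed because the list medians had opposite signs under the same contrast. Members of each list went both ways in each class. In macrophage-like cells the mean of the inflammatory genes was -0.09, and the median of all compared genes was 0.10. Each class had 1 library per group.

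Cells left out for mitochondrial UMIs also carried an origin. Host-class cells were 51.9% of the assigned ones at steady state (45.3 to 58.5%; 121 host-class and 112 donor-class of 271 cells) and 18.2% at day 7 (9.08 to 30.9%; 10 and 45 of 63 cells). They are listed because a signal of origin stood in cells that no comparison of genes or origin used; they entered only the class shares without a cell filter and the bound on the filters. Their median depths were 1006 and 975 UMIs.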

How the results depend on the processing

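Chosen only after the results were seen were the alternatives without any cell filter, with cluster 4 alone, with clear or at least 5 CD45 counts, without mast cell UMIs, and every alternative of the classical monocyte-like, macrophage-like and host-class over donor-class comparisons, which were moved to or added for these classes then. The lists, the comparisons of class shares, host-class shares, all cells and Ly6C-low monocyte-like cells, and the other alternatives of these were set before the data were examined. Unless a reason is given, the cause of a shift was not tested. No paired analysis was possible because each group had 1 library.

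The host-class share moved from 50.4% to 54.5% at steady state and from 11.5% to 18.99% at day 7 with the fixed threshold, to 55.2% and 14.4% with a mixture per library, and to 68.5% and 16.7% among monocyte-like and macrophage-like cells only; with no unassigned zone it was 15.2% at day 7. It fell at day 7 in each of these.

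The macrophage-like share fell at day 7 in every alternative of class shares, and its size moved. From 44.6% at steady state it went to 52.4% at resolution 0.5, 32.4% at resolution 1.5, 32.1% with doublet calls kept, 40.9% with the stricter filter, 41.1% with thinned cells and 28.6% without a cell filter. From 11.1% at day 7 it went to 13.5% at resolution 0.5, 7.33% at resolution 1.5, 7.27% with doublet calls kept, 8.94% with the stricter filter and 7.36% without a filter. The classical monocyte-like share at steady state (6.32%) became 8.04%, 3.93%, 2.26%, 1.985% and 1.46% at resolution 0.5, resolution 1.5, doublet calls kept, stricter filter and no filter. At day 7 (31.0%) it became 25.1%, 21.98%, 24.9%, 42.1% and 18.5% at resolution 1.5, doublet calls kept, stricter filter, thinned cells and no filter. The Ly6C-low monocyte-like share at steady state was 10.31% at resolution 0.5, 10.26% with doublet calls kept and 6.43% without a filter; at day 7 it was 16.4% with doublet calls kept. The cDC2-like share was 12.6% at steady state without a filter and 1.46% at day 7 with thinned cells. The basophil-like class was found again with doublet calls kept but in none of the other alternatives of class shares. The progenitor-like share at day 7 was 7.58% at resolution 1.5, 8.85% with the stricter filter and 9.01% without a filter. At resolution 0.5 and with thinned cells no progenitor-like class was found, and the neutrophil-like share at day 7 went from 2.66% to 12.3% and 11.07%.

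Over all cells, equalised class shares turned Cd36 to 0.42, Itgam to 0.19, and the list medians of scavenger receptors to 0.048, cell cycle to -0.11 and Ly6C-low monocyte markers to -0.28. The macrophage marker median became -0.63, and -1.98 with equal weight per cell. Equalising shares removes, by construction, what class shares contribute. Of its 73 values 46 moved, 5 reversed and 22 stayed.

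Keeping doublet calls clusters the cells anew, so class membership changes by construction. In Ly6C-low monocyte-like cells Fabp5 turned to -0.61 and the alternative activation median to -0.50. In host-class over donor-class macrophage-like cells at steady state C1qa turned to -0.26, Zfp36 to 0.49, and the medians of inflammatory genes to 0.52, immediate early genes to 0.34, complement to -0.016 and classical monocyte markers to -0.21; the class II median moved to -4.37. At day 7 Olfml3 turned to -1.37 and Fermt2 to -1.13. Of 338 values under this alternative 94 moved, 10 reversed and 234 stayed. Within cluster 4 alone the class II median was -1.76 and the classical monocyte marker median -0.31. Of 55 values in that cluster 24 moved, 1 reversed and 30 stayed.

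Equal weight per cell turned Vsig4 to -0.41, Pcolce2 to -0.77 and Timp2 to -0.057 in host-class over donor-class cells at day 7, where 8 donor-class cells set the value; of its 325 values 84 moved, 3 reversed and 238 stayed. Median-ratio scaling moved 10 of 325 values and reversed 0. The 100 CPM minimum moved 0 of 107 values, no minimum 1 of 127, and clear CD45 counts 17 of 55. Leaving out cells with mast cell UMIs moved 5 of 54. For antibodies, the centred log ratio and the unscaled medians moved 12 of 12 values each and reversed 0. The centred log ratio is in natural log units, but a change of unit alone would scale all values by the same factor. FrB went from -1.39 to -2.21, while CD200r3 went from 5.65 to 1.104 and CD215 from 3.25 to 0.44. The unit thus does not account for all the moves, and the sizes of the antibody changes depend on the measure.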

Other observations

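All tests in this part were chosen after the result was seen, except the one of chromosome 1 near Ptprc. The fall of macrophage-like and host-class cells at day 7 is the first pattern. Weaker staining at day 7 cannot be the whole cause, since the macrophage-like share set from RNA alone was 11.1% at day 7 against 44.6%. Neither can the cell filters, since counting every removed day 7 cell as macrophage-like gave 16.4% (14.4 to 18.5%), against 38.02% (35.8 to 40.2%) at steady state with every removed cell counted as another class. A leak of Ly6C-high cells alone at day 7 would leave the mix of the other cells alike. Macrophage-like cells were 43.8% (38.1 to 49.5%) of macrophage-like and Ly6C-low monocyte-like cells at day 7 and 84.6% (82.0 to 87.0%) at steady state. This cannot exclude dilution in which Ly6C-low monocyte-like cells, which rose from 8.10% to 14.2%, entered too. cDC2-like and fibroblast-like cells fell alongside macrophage-like cells, from 10.98% to 2.41% and from 4.17% to 1.42%. Loss of macrophages to clodronate may account for the fall, but each group was 1 preparation, so yield or gating differences remain open as well.

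The genes that differ between host-class and donor-class macrophage-like cells are the second pattern. A position of the cells in different clusters is argued against as the whole cause of the class II difference by cluster 4 alone. The class II median there was -1.76 (members from -2.12 to -1.50) against -3.02 in the class. Position may account for part, and for the immediate early and complement lists, at -0.13 and 0.18 in cluster 4. In cluster 7, outside the class, the class II median was -0.78 (members from -1.08 to -0.48). Weak or double staining is argued against by cells with clear CD45 counts (545 host-class, 30 donor-class). Among them the class II median was -2.66 (members from -3.41 to -1.78). These ranges run from the lowest to the highest member gene. They hold no counting error and no spread between cells, so they describe these cells only. Both medians come from UMIs summed over 39 and 30 donor-class cells, so neither test excludes that a few cells rich in class II set them. In the class, 5 of 54 donor-class cells held 69.9% of the MHC class II antibody counts at steady state. The CD11c antibody stood at 34.3 per 10000 in donor-class and 2.52 in host-class cells, with medians of 0 in both. A stretch of another strain's chromosome 1 around Ptprc cannot be told apart from chance: 2.0% of the 200 top genes lay within 20 Mb (4 genes, 0.548 to 5.04%) against 1.36% of all compared genes, and the upper bound passed the 4.09% set in advance as the limit for excluding it. No biological explanation was tested.

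Progenitor-like cells at day 7 are the third pattern. Marrow of the shielded ankle that stayed of host origin would carry host-class cells. Among progenitor-like cells with at least 5 CD45 counts, 2.11% (0.256 to 7.40%, 2 of 95 cells) were host-class, against 3.81% of classical monocyte-like cells. Marrow already held by donor cells would look donor-class too. The origin of the local marrow was not measured, so this speaks only against host-type marrow and does not exclude marrow in the preparation. Free RNA from lysed granulocytes, as the only source of these transcripts, would spread over all droplets. Instead, 86.0% of day 7 cells had 0 UMIs of Elane, 92.01% of Mpo, 93.4% of Ctsg and 74.3% (71.7 to 76.7%) of Prtn3. With these UMIs spread over all cells evenly or with their depth, it would be at most 5.86%, 17.3%, 48.97% and 8.64%. These genes are markers of that class, so this speaks only against free RNA as the sole source, not as a part. Of the tests tried before, 2 are not relied on: the Elane level of progenitor-like cells, since Elane is a marker of that class, and the ratio of Elane to S100a8, which was not highest in these cells (11281 to 166026 UMIs, and 324 to 3817 in cluster 13). Blood or recirculating donor marrow cells in the preparation may be the source, and this was not tested.

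Among the unnamed clusters, cluster 13 carried cell cycle genes (Top2a 562 CPM at steady state and 722 at day 7) and its host-class share was 28.6% and 4.26%. Cluster 11 carried Lyve1 (2042 and 1019 CPM) and Timd4 (96.6 and 87.9 CPM), with 36 host-class and 12 donor-class of 53 cells at steady state. Cluster 14 carried Cxcl10 (1495 and 770 CPM) in 57.1% and 63.6% of its 14 and 11 cells. Cluster 10 had a median depth of 1025 UMIs. The basophil-like cells of day 7 carried Mcpt8 (1662 CPM) and Hdc (7286 CPM).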
